A study of Danio rerio with 4 samples.

How the data were processed

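Brain tissue of zebrafish carrying a mutation in nop2, and of their siblings, was profiled by 2 assays with 1 library per genotype in each. Ribo-seq sequences the RNA fragments that ribosomes protect from nuclease and so counts ribosomes on messenger RNA. RNA bisulfite sequencing reads unconverted cytosines of messenger RNA as 5-methylcytosine (m5C). Groups were taken from the genotype in the labels. The sample titles give the age as 48 days after fertilization and the series' design text as 48 hours, and which is right could not be settled from the labels.

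Per the labels' protocols, frozen tissue was lysed, digested with RNase I and passed over size exclusion columns, fragments longer than 17 nucleotides were kept, and ribosomal RNA was removed with antisense DNA probes and RNase H. Per the submitters' processing notes, fastp, Bowtie2, STAR, Trimmomatic 0.38, HISAT2, SAMtools and methylKit were used with the genome build GRCz11, and the notes give neither the role nor the order of these tools. The program that counted footprints, the annotation release and the program behind the deposited Ribo-seq p-values were not given in the sources used here. The deposited bisulfite tables and their columns carry names of the program DSS, whose version and settings were not given in the sources used here.

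The deposited Ribo-seq table held, per the file headers, a count per gene and library, and 25.7% of its 25522 genes had a count that was not a whole number, so the deposited values were read as the authors' expected counts, reads assigned to genes by an estimate and not normalized. Expected counts were rounded to whole numbers before use. The deposited table also gave TPM, which the authors scaled by gene length and library, per library, a log2 fold change equal to the log2 ratio of mutant over sibling TPM with zeros set by the authors to 0.001, and a p-value and FDR for each gene. Those p-values compare 1 library with 1 library, and the authors' test behind them was not given in the sources used here. Rounded counts summed to 20696345 in the sibling library and 18884879 in the mutant library, so that 1 read was worth 0.0483 and 0.0530 CPM, the count of a gene scaled to the library total.

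The 2 deposited bisulfite tables listed differential cytosines and differential regions that had passed a threshold of the authors, with a smoothed methylation fraction from 0 to 1 for a condition 1 and a condition 2, their difference, a standard error and an unadjusted p-value per locus. The values of the file bore out that the difference was condition 1 minus condition 2. No header or label tied these conditions to a genotype, so no direction by genotype was given. The rows of both tables did not line up with their header, and columns were assigned after testing these relations on the values. Coverage and the bisulfite conversion rate were not used here, so the depth behind each level was unknown and no interval was computed. Positions were read as intervals counted from 0 and are printed counted from 1, and a shift by 1 base could not be excluded. Gene spans came from the tables, and no annotation of GRCz11 was used here, so loci were not split into exons, introns or untranslated regions.

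For each gene the log2 ratio of mutant over sibling CPM was computed from counts plus a pseudocount of 0.5, and genes with a mean of at least 1 CPM over both libraries were kept. A 95% interval of each ratio came from the exact Clopper-Pearson interval conditional on the sum of both counts. Intervals cover counting error only and treat each read as independent. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow. With 1 library per genotype no difference had a replicate check, and no p-value across genes was computed. Each gene list was described by the median log2 ratio of its measured genes, an exact 95% order-statistic interval over genes, and the percentile of that median among 10000 random lists of the same size matched on mean CPM in 20 bins. Random lists were drawn from all kept genes, those of the list included, and with replacement in large bins. A fold against a library with no read was computed against a floor of 3 counts in that library.

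The 26 gene lists were written before the data were examined and cover cytosolic 60S and 40S ribosomal proteins, mitochondrial ribosomal proteins, small subunit processome and 40S assembly factors, 60S assembly factors, small nucleolar ribonucleoprotein (snoRNP) core proteins, RNA polymerase I machinery, m5C writers, readers and oxidases, p53 targets, the integrated stress and unfolded protein responses, translation factors, proteasome subunits, nuclear and mitochondrially encoded oxidative phosphorylation, cell cycle genes, neural progenitors, proneural genes, differentiated neurons, oligodendrocyte lineage, lens and retina, skeletal muscle, epidermis, blood cells, microglia, endothelium, and cartilage with mesenchyme and notochord. Of 1465 list entries, 1395 matched a gene of the table, 46 of them through another name of the same gene in reference gene name tables, of which the RefSeq table follows the assembly GRCz12tu. The 6 lists added after the data were seen are used in the closing section.

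Genes named in the text followed a rule set before the data were examined. It takes nop2, the 8 largest and the 8 smallest ratios among genes with a gene name and a mean of at least 10 CPM, and from each list the 2 genes with the largest absolute ratio and the most abundant gene at that minimum. For m5C it takes the 5 genes with most loci, the 3 loci with the largest difference in each direction, and the 3 regions with the largest area statistic in each direction. Other genes are said to be chosen after their values were seen.

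The ratio and interval steps were tested on counts simulated from the real genes with 200 changed genes for the comparison of the mutant with the sibling Ribo-seq library. The simulated counts held counting error only, with no variation between animals or libraries. The rates below therefore do not cover false calls that such variation would give. Over 18107 simulated genes, 98.9% of 91 genes changed by a log2 value of 1.5 and 100% of 101 genes changed by 2 were recovered at a ratio of at least 2-fold, 0.112% of unchanged genes passed it, and 95.8% of counting intervals held the true value. The random-list step was checked on the ratios of the real counts. Among 200 random lists of 40 genes drawn from them, 7% lay outside the 2.5th to 97.5th percentiles.

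Alternatives scaled the libraries by edgeR TMM factors (1.02 sibling, 0.981 mutant), by DESeq2 size factors (1.07 and 0.937), or by totals without the 20 most abundant genes. Others used the authors' TPM values with a pseudocount of 1, no filter beyond 1 read, a minimum of 10 CPM, a pseudocount of 5, or unmatched random lists, and stricter thresholds on the methylation lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used.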

Results

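Ribosome footprints and RNA methylation were compared between brain tissue of nop2 mutant zebrafish and of their siblings. Nop2 is a nucleolar RNA methyltransferase that takes part in the assembly of the large ribosomal subunit, and the series asks how its loss affects ribosome formation and neural differentiation. Each assay had 1 sibling and 1 mutant library, so no difference below had a replicate check. The Ribo-seq libraries held 20696345 (sibling) and 18884879 (mutant) footprint reads. Of 25522 listed genes, 23055 had at least 1 read and 18127 reached a mean of 1 CPM. The labels describe the material as whole brain cells, and genes of muscle, yolk and skin were also abundant in both Ribo-seq libraries.

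The mutated gene was checked first. Footprints on nop2 (ENSDARG00000043304) numbered 657 in the sibling library (31.7 CPM) and 41 in the mutant library (2.17 CPM), a log2 ratio of -3.85 (95% counting interval -4.36 to -3.41), after rounding of estimated counts that were not whole numbers. Of the 18127 genes, 856 were at least 2-fold higher and 1034 at least 2-fold lower in the mutant library, and the median gene had a log2 ratio of -0.06. Which direction held more genes depended on the setting, with 982 higher and 921 lower under TMM scaling, 982 and 924 under DESeq2 size factors, and 362 and 333 at 10 CPM or more. Genes of ribosomal proteins, ribosome assembly, the p53 target list, skin and blood lay higher in the mutant library, and genes of eye, muscle, cartilage and mature neurons lay lower. Among genes with a gene name and a mean of at least 10 CPM, the largest ratios belonged to Igdcc3 (2.75 to 48.6 CPM, log2 ratio 4.13), mustn1b (3.73), the small heat shock protein gene hspb9 (3.42), bmb (3.30), the embryonic globin gene hbbe3 (3.29), the cell cycle inhibitor gene cdkn1a (3.26), RNF14 (ENSDARG00000078683, 3.04) and rps27l (2.94). At the same minimum the smallest ratios belonged to the lens crystallin gene crygm2d11 (148 to 0.953 CPM, log2 ratio -7.24), the cartilage matrix gene matn1 (-6.93), the G protein beta subunit gene gnb3a (-6.08), 1 of 2 genes annotated as znf488 (ENSDARG00000092269, -5.52), the retinoschisin gene rs1a (-5.05), the rhodopsin gene rho (-5.01), crygm2d16 (-4.73) and the muscle creatine kinase gene ckmt2a (-4.49). The deposited description of this znf488 gene differs from its symbol and reads PR domain zinc finger protein 8-like. The crystallin genes crygm2d11 and crygm2d16 belong to a gene family and had counts that were not whole numbers. The authors' deposited table gave nop2 a log2 fold change of -3.91 and listed 9871 genes with an FDR under 0.05, of which 1001 had a log2 fold change of at least 1 and 1557 of at most -1. Of the 2558 genes past both limits in the authors' deposited table, 647 lay under the minimum of 1 CPM used here. No total RNA counts were analysed here, so a ratio of footprints holds both transcript abundance and ribosome load.

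**Figure D1:**
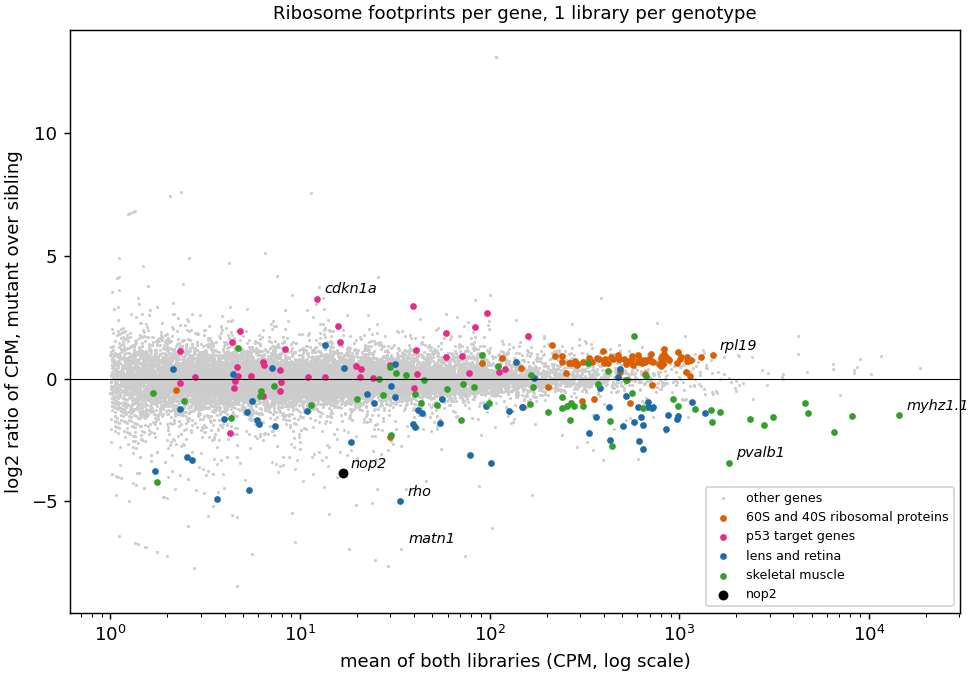
Each point is a gene with a mean of at least 1 CPM, placed by its mean over both libraries (log scale) and by its log2 ratio of mutant over sibling CPM, and colours mark 4 gene groups and nop2. Ribosomal protein genes sit mostly above 0 (medians 0.73 for both subunits), and the most abundant muscle gene, myhz1.1, sits at -1.48.

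Most genes of ribosomal proteins and of the factors that assemble ribosomes carried more footprints in the mutant library, while nop2 and some others carried fewer. Of 47 measured 60S ribosomal protein genes 43 were higher, with a median log2 ratio of 0.73 (95% interval 0.67 to 0.80), and of 34 measured 40S genes 29 were higher, with a median of 0.73 (0.64 to 0.84). Both medians lay at percentile 100 among 10000 random lists matched on abundance. The 60S genes took 2.17% of sibling and 3.43% of mutant reads, and the 40S genes took 1.48% and 2.33%. The ratio was 0.95 for rpl19, the most abundant 60S gene, 0.75 for rps3a, the most abundant 40S gene, and 1.19 for rpl11. Among the 4 lower 60S genes was rplp2, with 50.0 CPM in the sibling and 9.58 CPM in the mutant library (-2.38). Factors of the small subunit processome had a median of 0.37 (0.29 to 0.42; 55 of 61 higher), with utp4 at 0.87, ddx52 at 0.76 and the abundant nolc1 at 0.42. Factors of 60S assembly had a median of 0.39 (0.29 to 0.48; 63 of 68 higher), with rrp8 at 0.93 and the abundant nucleolin gene ncl at 0.05, which became -0.0043 with the authors' TPM values. Both assembly lists lay at percentile 100. The snoRNP core proteins, parts of the particles that modify ribosomal RNA, had a median of 0.26 (0.12 to 0.44, percentile 98.4), with nop10 at 1.11, dkc1 at 0.60 and the fibrillarin gene fbl at 0.44. RNA polymerase I machinery had a median of 0.54 (0.15 to 0.70, percentile 99.99), with polr1d at 0.83 and polr1a at 0.74, whereas the abundant ubtf stood at -0.18. Mitochondrial ribosomal proteins were divided evenly, 38 higher and 38 lower, with a median of 0.01 (-0.07 to 0.05, percentile 87.1), although mrpl24 (0.60), mrpl42 (0.59) and mrps18b (0.56) were higher. Translation factors had a median of 0.12 (0.02 to 0.19, percentile 98.0), with eef2k at 0.60, eif2s2 at 0.54 and the elongation factor gene eef1a1l1 at 0.22.

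The p53 target genes, a list of cell cycle arrest, cell death and repair genes, were higher in the mutant library as a group. Of 41 measured targets 33 were higher and 13 at least 2-fold higher, with a median of 0.39 (0.10 to 0.93, percentile 100). Footprints on the cell cycle inhibitor gene cdkn1a stood at 2.32 CPM in the sibling and 22.4 CPM in the mutant library, and on rps27l at 9.04 and 69.7 CPM (2.94). Other targets, chosen after their values were seen, were ccng1 (2.67), casp8 (2.14), the ubiquitin ligase gene mdm2 (2.09), the cell death gene bbc3 (1.95) and the nucleotide synthesis gene rrm2b (1.85). The related gene mdm4 went the other way (-2.23). Genes of the integrated stress and unfolded protein responses did not move together. Their median was 0.03 (-0.29 to 0.21, percentile 78.8), with 6 of 47 at least 2-fold higher and 3 at least 2-fold lower. The transcription factor gene cebpb (1.69) and nupr1a (1.39) were higher, and the chaperone gene canx (-0.52), the most abundant of the list, was lower. The enzymes and binding proteins of RNA m5C, a list that includes nop2, were divided evenly, 8 higher and 8 lower, with a median of -0.06 (-0.21 to 0.31, percentile 42.9). Among them the abundant m5C reader gene ybx1 stood at -0.18 and the oxidase gene tet1 at -0.74. Members chosen after their values were seen went both ways. The writer genes nsun2 (0.47), nsun4 (0.69) and nsun5 (0.31) and the reader gene alyref (0.41) were higher, with counting intervals above 0. The genes tet2 (-0.21), tet3 (-0.16) and fmr1 (-0.29) were lower, with counting intervals below 0. Counting intervals of nsun3 (0.17), nsun6 (0.09) and trdmt1 (-0.15) included 0.

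Genes of mature neurons carried fewer footprints in the mutant library, and genes of earlier steps were divided. Of 136 measured genes of differentiated neurons 112 were lower, with a median of -0.34 (-0.45 to -0.26, percentile 0). Their summed share was 2.39% of sibling and 1.88% of mutant reads. The synaptic genes syt5b (48.1 to 5.67 CPM, -3.08) and stxbp1b (-2.65) had the lowest ratios at 10 CPM or more, and the abundant tubulin gene tuba1a stood at -0.27. The pan-neuronal gene elavl3, chosen after its value was seen, differed little (386 to 396 CPM, 0.04). Proneural and commitment genes had a median of 0.10 (-0.16 to 0.39, percentile 98.1), with 7 of 59 at least 2-fold higher and 6 at least 2-fold lower. The transcription factor genes pou4f2 (-2.32) and neurod1 (169 to 43.2 CPM, -1.97) were lower, and the abundant sox11a stood at -0.01. Members chosen after their values were seen included neurod6b (-1.89) and neurod6a (-2.30) on the lower side, and atoh1b (1.41), the Notch ligand genes dlb (1.33), dld (1.18) and dla (1.04), and ascl1a (0.67) on the higher side. Neural progenitor and radial glia genes had a median of 0.08 (-0.12 to 0.26, percentile 96.2). There prom1b (25.9 to 2.17 CPM, -3.56) and the radial glia gene fabp7a (800 to 252 CPM, -1.67) were lower, and the most abundant member, hmga1a, stood at -0.27. Among progenitor genes chosen after their values were seen, notch1a was at 1.00 and her15.1 at 1.09. Cell cycle and DNA replication genes were slightly higher, with a median of 0.14 (0.08 to 0.20, percentile 99.9; 62 of 88 higher), with hmgb2b at 0.29, nusap1 at 0.71 and dut at -0.67. Oligodendrocyte lineage genes had a median of -0.21 (-0.66 to 0.38, percentile 11.7), with pdgfra at -0.78, cspg4 at -0.66 and cnp at -0.46. The lower ratios of neuronal genes stood beside lower ratios of retinal genes, and neurod1, pou4f2 and prom1b are also expressed in the retina.

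Among markers of other tissues, those of eye and muscle were lower in the mutant library and those of skin and blood higher. Of 63 measured lens and retina genes 53 were lower and 44 at least 2-fold lower, with a median of -1.35 (-1.66 to -1.15, percentile 0). The lens gene crybb1 took 1977 CPM in the sibling and 749 CPM in the mutant library (-1.40), rho took 65.5 and 2.01 CPM, and the bipolar cell gene vsx1 took 187 and 17.2 CPM (-3.44). Of 63 skeletal muscle genes 52 were lower, with a median of -0.98 (-1.12 to -0.61, percentile 0), and their summed share was 9.43% of sibling and 3.57% of mutant reads. The myosin gene myhz1.1 alone went from 21336 to 7625 CPM (-1.48), myhz2 had a ratio of -2.74 and the calcium buffer gene pvalb1 of -3.42. All 3 belong to gene families and had counts that were not whole numbers. Cartilage, mesenchyme and notochord genes had a median of -0.41 (-0.60 to -0.21, percentile 0), with matn1 at -6.93, col2a1a at -0.52 and the fibronectin gene fn1b at 2.27. Epidermis and periderm genes had a median of 0.45 (0.28 to 0.63, percentile 100), with the keratin gene krt4 at 0.81 (6520 to 11426 CPM), agr1 at 1.46 and icn2 at 1.35. Blood cell genes had a median of 0.45 (0.28 to 0.74, percentile 100), with the globin genes hbbe3 (72.3 to 705 CPM) and hbae1.2 (0.89) and with blvrb (0.95). Endothelial genes had a median of 0.26 (0.07 to 0.41, percentile 99.99), although tal1 (-1.15), mfsd2ab (-0.77) and aqp1a.1 (-0.27) were lower. Microglia and macrophage genes had a median of 0.10 (-0.29 to 0.37, percentile 90.8), with ctss2.1 at 1.69, hmox1a at 1.32 and the lipoprotein gene apoeb at 0.89.

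Genes of energy metabolism and protein turnover differed by little between the libraries. Nuclear encoded genes of oxidative phosphorylation had a median of -0.10 (-0.16 to -0.05, percentile 2.13; 60 of 83 lower), with cox4i2 at -0.94, ndufs8a at -0.64 and the abundant atp5fa1 at -0.42. The 13 mitochondrially encoded genes had a median of -0.15 (-0.34 to 0.16, percentile 9.18), with mt-atp8 at -0.55, mt-atp6 at -0.50 and mt-co1 at 0.22. Proteasome subunits had a median of -0.01 (-0.08 to 0.06, percentile 45.2), with psmd9 at 0.50, psma6b at 0.39 and psmd1 at -0.24.

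**Figure D2:**
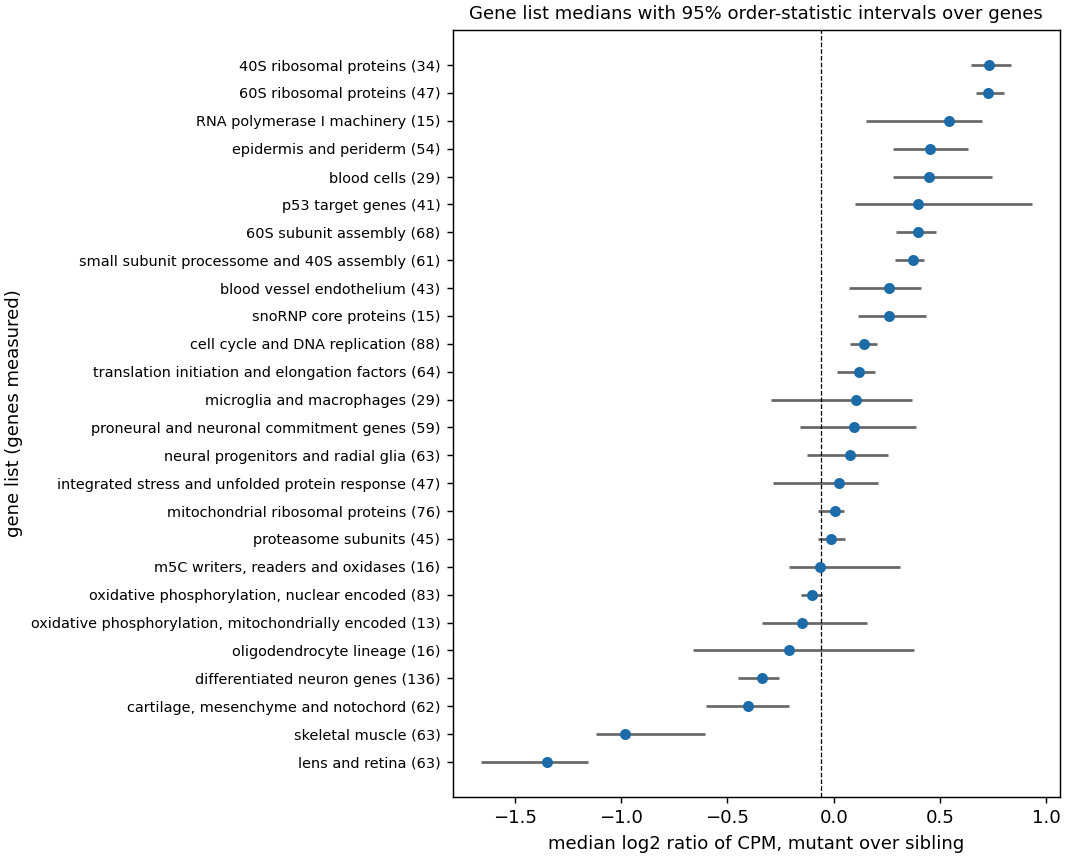
Each point is the median log2 ratio of mutant over sibling CPM over the measured genes of 1 of the 26 gene lists, with the number of genes in parentheses, the bar is the exact 95% order-statistic interval over genes, and the dashed line is the median of all genes (-0.06). Ribosomal protein lists stand highest (0.73) and the lens and retina list lowest (-1.35).

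Differential m5C loci lay within the spans of 92 genes, among them the deubiquitinase gene usp22, the atypical protein kinase C gene prkcz and the axon guidance gene slit1a. Of the 617 distinct loci in the authors' deposited table, 499 had a higher level in condition 1 and 118 in condition 2, a share of 80.9% for condition 1. Which of these conditions is the mutant was not given in the sources used here. Loci higher in condition 1 had a median level of 0.350 in that condition and of 0.00045 in condition 2, per the authors' deposited table. Those higher in condition 2 had medians of 0.00059 in condition 1 and 0.366 in condition 2 in the authors' deposited table. The lower of both levels was under 0.01 at 583 loci (94.5%) of the authors' deposited table. The 5 genes with most loci in the authors' deposited table were usp22 (33 loci), fbxo8 (28), prkcz (24), the heparan sulfate polymerase gene ext1b (22) and the interleukin receptor-like gene il1rapl2 (19), together 126 loci. Toward condition 1, many loci of the authors' deposited table were tied near the largest difference, among them single loci in si:ch211-11n16.2 (chromosome 15, position 14408151), ek1 (chromosome 24, position 27596773) and slit1a (chromosome 13, position 599225), each 0.730 with a standard error of 0.311. Of the loci of reep3b on chromosome 12, chosen after their values were seen, 8 had the same difference of 0.730 with a smaller standard error of 0.103 in the authors' deposited table. Toward condition 2, the authors' deposited table listed edc4, a messenger RNA decapping factor gene (chromosome 18, position 21886820, difference -0.732, standard error 0.310), and 2 loci of the deacetylase gene sirt6 (chromosome 2, positions 53083971 and 53084029, difference -0.577, standard errors 0.160 and 0.234). The gene nop2 had no locus in the authors' deposited table, and of the 26 gene lists only skeletal muscle held genes with loci, namely desma and eno3. Loci were not adjusted for multiple testing in the values used, whose largest p-value in the authors' deposited table was 0.0200.

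Differential m5C regions gathered these loci into short stretches. The authors' deposited table held 52 distinct regions on 51 genes, 41 higher in condition 1 and 11 higher in condition 2, and 510 of the 617 loci (82.7%) lay inside a region. Regions of the authors' deposited table spanned 55 to 518 bases (median 116.5) and 4 to 33 cytosines (median 7.5). The region of usp22 (chromosome 12, 1524838 to 1525318, GRCz11) had 33 cytosines and mean levels of 0.305 and 0.00031 in conditions 1 and 2 in the authors' deposited table. The prkcz region (chromosome 8, 17679882 to 17680059) had 24 cytosines and levels of 0.397 and 0.00053, and the fbxo8 region (chromosome 1, 38356085 to 38356359) had 28 cytosines and levels of 0.249 and 0.00021, per the authors' deposited table. Toward condition 2, the authors' deposited table listed regions in il1rapl2 (chromosome 14, 10126920 to 10127091, 19 cytosines, levels 0.00059 and 0.264) and si:dkey-35m8.1 (chromosome 5, 62235220 to 62235322, 15 cytosines, levels 0.0746 and 0.391). The phosphatase gene phlpp1 (chromosome 2, 262689 to 262819, 8 cytosines) had levels of 0.00039 and 0.549 in the authors' deposited table. Regions lay within the spans of the genes listed with them, and their place in exons or introns was not analysed here.

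**Figure D3:**
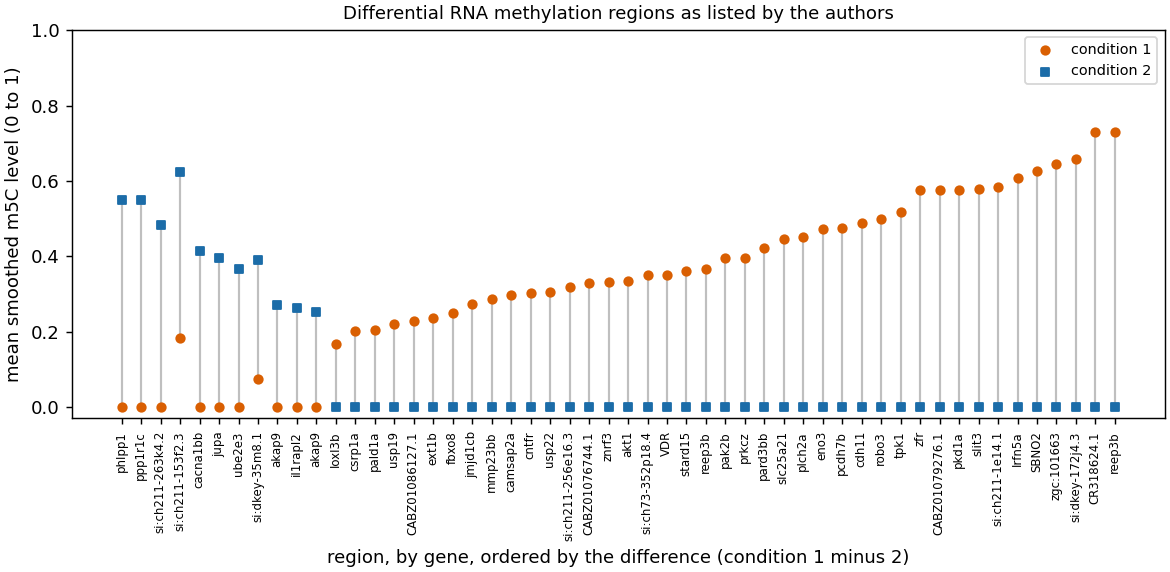
Each of the 52 regions is placed on the horizontal axis under its gene and ordered by difference, with its mean smoothed m5C level (0 to 1) in condition 1 (circles) and condition 2 (squares), as the authors' deposited table gives them. In 41 regions condition 1 is higher and condition 2 lies near 0.

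Genes with m5C loci were then looked up in the Ribo-seq libraries. The 59 measured genes with loci higher in condition 1 had a median log2 footprint ratio of -0.17 (-0.37 to -0.07), at percentile 3.2 among matched random lists, and 41 of them were lower in the mutant library. The 16 measured genes with loci higher in condition 2 had a median of -0.05 (-0.17 to 0.16), at percentile 49.0. Individual ratios were -0.12 for usp22, -0.05 for prkcz, -0.43 for fbxo8, -0.63 for ext1b and 0.43 for slit1a. The gene il1rapl2 had 21 reads in the sibling and 12 in the mutant library. It lay under the minimum of 1 CPM, so it was not among the measured genes. Those of edc4 and sirt6 were -0.12 and 0.04. The counting intervals of usp22 (-0.32 to 0.09), prkcz (-0.29 to 0.19), fbxo8 (-1.02 to 0.14) and sirt6 (-0.11 to 0.19) included 0. Loci anywhere in the gene body were used, since loci on exons could not be separated here.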

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

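The scaling without genes of the eye, muscle, skin, blood and cartilage lists, and random lists matched on length, were chosen after the data were seen; the other settings were set before. No paired analysis was possible because each assay had 1 library per genotype, so the groups shared fewer than 2 replicate numbers, and leaving out a library was impossible for the same reason. Splits of loci by exon and by canonical transcript were not run, since no annotation of the build was used here. Of 208 recomputed list medians 192 stayed inside the interval of the main value, and no median whose interval excluded 0 changed sign. Lists near 0 did cross it over the planned settings, from -0.104 to 0.0809 for the stress response, -0.0143 to 0.204 for microglia, -0.0516 to 0.0601 for mitochondrial ribosomal proteins and -0.0662 to 0.0434 for proteasome subunits. Scaling by TMM and by DESeq2 size factors moved the median of all genes from -0.06 to -0.00279 and -0.00308. Under these factors, respectively, the medians were 0.0601 and 0.0598 for mitochondrial ribosomal proteins, 0.43 and 0.43 for the small subunit processome, and -0.0480 and -0.0482 for nuclear encoded oxidative phosphorylation. With the authors' TPM values and a pseudocount of 1 TPM, the 60S ribosomal proteins stood at 0.66 and nuclear encoded oxidative phosphorylation at -0.16. In that setting nop2 stood at -2.93 and ncl at -0.0043. The authors' own ratio of the same TPM values, with zeros set to 0.001, was -3.91 for nop2. The pseudocount of 1 TPM thus brought nop2 to -2.93, and the cause of the other shifts was not tested. Among named genes ncl was the only one to change sign with a counting interval that excluded 0, and sox11a, whose interval included 0, stood at 0.0452 with TMM and 0.0449 with DESeq2 size factors. Totals without the eye, muscle, skin, blood and cartilage genes gave 0.62 for 60S and 0.63 for 40S ribosomal proteins, -0.10 for mitochondrial ones, 0.27 for the processome, 0.29 for 60S assembly, -0.11 for proteasome subunits, -0.20 for nuclear encoded oxidative phosphorylation and 0.0424 for the cell cycle, all by 1 common shift. The oxidative phosphorylation percentile became 23.0 with unmatched random lists, and that of proneural genes 96.0 with lists matched on length.

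Against 856 genes higher and 1034 lower, the counts of genes at least 2-fold higher and lower were 982 and 921 with TMM and 982 and 924 with DESeq2 size factors, so more genes were then higher than lower. They were 654 and 1188 without the eye, muscle, skin, blood and cartilage genes, and 2082 and 2498 without the filter. With TPM they were 453 and 656, but that setting also used a pseudocount of 1 TPM and kept 17587 genes. These changes were not separated. The counts were 362 and 333 at 10 CPM or more, and 365 and 516 where the whole counting interval lay beyond 2-fold. The last 2 test fewer genes or ask more of each, by construction. Loci higher in condition 2 numbered 73 at a p at least 10 times smaller than the largest in the authors' deposited table, against 118; with 1 locus per gene 71 and 20 remained in the 2 directions. Regions higher in condition 2 numbered 7 at 5 or more cytosines, against 11. Depth limits single genes most near 1 CPM, where about 20 reads stand behind a value, and the depth behind methylation levels was unknown.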

Other observations

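The pathway scan, the 6 added gene lists and all tests of this part were chosen after the results they bear on were seen, although the scalings they use were set before. Among 286 pathways of the deposited annotation with at least 15 measured genes, glutamatergic synapse had the lowest median (-0.53, interval -0.96 to -0.09, 37 genes), with the photoreceptor transducin gene gngt2b at -5.19, the vesicular transporter gene slc17a7a at -2.78 and the glial transporter gene slc1a3b at -1.13. The circadian rhythm pathway also lay low (-0.40, -0.75 to -0.13, 27 genes), led by the nuclear receptor genes rorab (39.9 to 7.89 CPM, -2.33), roraa (ENSDARG00000031768, -1.74) and rorb (62.9 to 22.3 CPM), with the clock gene per3 at -1.05. GABAergic synapse, which also holds gngt2b, had a median of -0.40, with the transporter gene slc6a1b at -1.15. How far retinal genes lowered both synapse medians was not tested, and photoreceptor genes had a median of -1.84. The highest medians belonged to the coronavirus disease pathway (0.80) and to glycosphingolipids of the lacto and neolacto series (0.66), followed by complement and coagulation cascades at 0.63 (interval 0.28 to 0.91, 49 genes, 15 at least 2-fold higher), with c6.2 (20.1 to 115 CPM, 2.51), proca (2.04), clu (1.96) and serping1 (1.66). The coronavirus disease pathway shares c6.2, C7 (1.89) and cfd (1.68) with the complement pathway and also holds rps27l (2.94). These pathways are therefore not independent observations.

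Genes of yolk, liver and intestine took 4.18% of sibling and 5.56% of mutant reads, although the labels describe brain. Their median was 0.51 (0.32 to 1.06, percentile 99.99), with the lipoprotein gene apobb.1 at 15828 and 21308 CPM, the fibrinogen gene fgb at 1.11 and the vitellogenin genes vtg1 (4.18) and vtg7 (2.82), whereas the liver gene fabp10a was at -6.00. None of the 33 genes of that list was in another list. Genes of hatching enzymes, he1.1 (127 to 258 CPM, 1.02) and he1.2 (0.84), and the cathepsin genes ctsla (1973 to 6525 CPM, 1.73) and ctslb.4 (1.98) were also higher in the mutant library. Hatching enzymes, embryonic globins and yolk genes are known from embryos, so they bear on the age and on the tissue in the libraries, and neither was tested. In the sibling library 2 genes without a symbol (ENSDARG00000112047 and ENSDARG00000116179) had no read, against 215 CPM for each in the mutant library, at least 1484-fold higher. Both had the same count of 4062, and the cause was not tested.

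Eye and muscle genes were lower in the mutant library, and the tables argue against 1 narrow technical account of it, an equal loss of all non-brain tissues. If the mutant sample held less of all non-brain tissues alike, their lists would lie on 1 side, yet the epidermis median had an interval from 0.28 upward. Tissues can be kept or lost separately in a dissection, so a different cut stays open with 1 library per genotype. Under TMM, DESeq2 and trimmed totals the highest of the muscle and the lens and retina medians was -0.93. Each of these scalings moves all genes by 1 small common shift, so they could hardly have raised these medians and decide nothing. Less carried-over muscle stays open and cannot be told apart from a change in muscle. From the 25th to the 75th percentile the 30 contractile genes at 10 CPM or more spanned 0.76 on the log2 scale, from -1.63 to -0.87. That is under the limit of 1 set for a difference by a common factor but does not exclude a change in muscle. In 28 of these 30 genes the counting interval excluded their common median, so their ratios differed by more than the counting error of independent reads. A candidate explanation is that later differentiation was more affected than early steps, since early genes exceeded late ones by 0.83 in muscle (-0.38 against -1.21) and by 1.53 in retina (-0.32 against -1.84), with intervals that did not overlap. Slower development of the mutant or a different dissection may give the same order, and 4 of 9 early retina, 4 of 11 early muscle, 13 of 30 photoreceptor and all 36 contractile genes were also in earlier lists.

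Ribosomal protein genes stood higher in the mutant library. The values argue against gene length, and against an equal rise of all messenger RNAs with a terminal oligopyrimidine tract, as the whole cause. Whether scaling by the library total gave the difference was not settled. The ribosomal protein medians were at least 0.72 under TMM, DESeq2 and trimmed totals. Each of these moves all genes by 1 small common shift, so they could hardly have lowered the medians much and do not test the scaling account. Over all planned settings the 60S median ran from 0.66 to 0.78 and the 40S median from 0.67 to 0.79. Random lists of the same abundance and effective length had an upper bound of 0.41, below both medians, and medians of up to 0.17, and since ribosomal protein genes were not left out of the draws no share was assigned to gene length. Other messenger RNAs with a terminal oligopyrimidine tract, which are translated under the same control, had a median of 0.22 (0.10 to 0.46, percentile 93.3). That interval ended below those of the ribosomal protein lists, which began at 0.67 (60S) and 0.64 (40S), and this argues against an equal rise. The median lay under 0.36, which is 0.5 of the ribosomal protein median, but the interval included 0.36. A smaller rise of these messenger RNAs stays open, since 15 of the 19 genes were higher. Of the 19 genes, 15 were also in earlier lists. A response to the loss of nop2 was not tested and stays open, as do transcript abundance, ribosome load and a different make-up of the samples, since epidermis (0.45), blood (0.45) and yolk, liver and intestine genes (0.51) were also higher.

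Methylation loci came in short blocks at 1 level. When loci up to 100 bases apart were joined, the 617 loci of the authors' deposited table made 98 blocks, and 91.6% of loci shared both levels with another locus of their block, as smoothing by the authors would give. Levels from few reads could also be involved: in 23.5% of blocks of the authors' deposited table the higher level recurred to 6 decimals on another chromosome, for example 0.731 in 7 blocks on 6 chromosomes, but this falls between the bounds set and the depth is unknown. Unconverted stretches of RNA cannot be told apart from true methylation, since 69.4% of loci had another within 10 bases in the authors' deposited table but smoothing alone lists neighbours together. No biological explanation was tested for these blocks, because the conditions were not tied to a genotype.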
